A study of Caenorhabditis elegans with 2 samples.

How the data were processed

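Anti-GFP ChIP-seq of late embryos of strain OP615 was represented by 2 biological replicates in 1 group, grouped by the gene named as the target of the insertion and by stage, per the labels. Per the deposited file listing, the authors called a relaxed peak list for each replicate and for the alignments of both replicates pooled, each against a control, and then derived a list thresholded by reproducibility (IDR). All lists were deposited in 2 genome builds, ce11 and ce10. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. Read numbers are not given either, so depth is unknown and no interval that needs it was made. The control was not analysed here.

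The deposited lists give for each peak a signal value and a −log10 q value from the authors' caller, with the position of the summit. Signal is the authors' value per peak on a scale set within each list, so it was used only to rank or describe peaks within a list. The −log10 q values reached at most 2.36 in the ce11 pooled list and were used for nothing. Because the relaxed lists were made to hold background as well as peaks, overlap with a full list says little. Comparisons of replicates therefore used the 469 peaks of highest signal of each, N being the number of thresholded ce11 peaks. The thresholded peaks were checked to be the N pooled peaks of highest signal in ce11, and in ce10 (449 peaks) likewise, so a place in that list reflects pooled signal and not rank in each replicate. Peak widths were 380 bp in the thresholded list except for 38 narrower peaks, which sets the resolution.

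Positions were compared with Ensembl release 115 gene models of WBcel235, which is the ce11 sequence, and with the RefSeq sequence and products of the same assembly. No peak ran past a chromosome end. Coordinates are in ce11, counted from 1, and none were converted between builds. The annotation was not used with ce10. Each summit was put in 1 class in the order promoter (500 bp upstream to 100 bp downstream of the 5′ end of a protein-coding gene), exon, intron, intergenic. Small non-coding RNA genes were those of biotype tRNA, snRNA, snoRNA or rRNA within 200 bp. Shares were tested by 100000 circular shifts of summits within each chromosome (permutation test, two-sided). They were also tested by Fisher's exact test against the 28330 pooled peaks that overlapped no thresholded peak by 1 bp or more. Background peaks had lower signal by construction. Intervals are exact Clopper-Pearson 95% intervals over peaks or genes and cover counting error only. Peaks are sites in 1 set of samples and not replicates, so no p-value here measures the spread between animals. Replicate overlap used the same shifts, one-sided.

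Genes were assigned to the nearest protein-coding 5′ end within 1000 bp. The background was the 8436 genes that got a pooled peak by that rule, and 22 gene lists were tested by Fisher's exact test (two-sided, Benjamini-Hochberg over the lists). Chromosome shares were tested against length (exact binomial) and against background peaks. Canonical 6-mers were counted as present or absent within 50 bp of the summit and compared by Fisher's exact test with 3 background windows per peak from the same 5-point bin of GC content. Peaks within 20 kb of Y22D7AL.16 and unc-119 were compared with 100000 random windows of the same chromosome (one-sided). The genes named are both transgene genes, the 25 protein-coding genes at the strongest thresholded peaks overlapped in both replicate lists, and up to 4 bound genes per list by signal. Also named are the 5 non-coding RNA genes nearest the strongest peaks, and the 5 6-mers of lowest adjusted p in each direction. These rules, the lists and all tests in the report were fixed before the data were examined, except where stated.

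Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and matplotlib 3.10.9 for figures. The procedures were tested on simulated data. In 20 sets of 469 random positions, each with 2000 shifts, 1 gave p under 0.05 by the permutation test for promoters. With 93 positions put in promoters, 136 were counted there, 43 of them among the unplanted ones. Of 469 simulated peaks of which 234 were shared, 234 were found to overlap. In 20 draws of 253 random genes from the 8436, 2 lists passed in all, and with 15 nuclear hormone receptor genes planted that list passed (Fisher's exact adjusted p = 1.91e-05) and no other did. In 469 background windows against matched windows 0 of 2080 6-mers passed, and a 6-mer planted in 46 windows was the only 1 that passed.

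Alternatives changed the build, the overlap rule, N, the promoter window, the distances, the backgrounds and the peak set (the upper 234 peaks, the 295 supported by both replicates' top peaks, or the top peaks of 1 replicate alone). With 1 group there was no test between groups, and outlier tests of samples do not apply to 2 samples.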

Results

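Binding of the tagged protein Y22D7AL.16 was mapped by ChIP-seq in Caenorhabditis elegans embryos of the strain OP615, which carries the unc-119(tm4063) mutation on chromosome III and an integrated transgene, wgIs615. The transgene expresses Y22D7AL.16 with a GFP-FLAG tag at its C terminus. RefSeq describes the product of Y22D7AL.16 as a protein with a zinc finger domain of the C2H2 type. Whole late embryos of both sexes were collected 4.5 h after synchronization by egg bleaching, and chromatin was precipitated with an antibody against GFP. There were 2 biological replicates and 1 group, so the question was where the tagged protein was found in the genome at this stage, and no condition was compared with another. The data analysed were lists of called peaks in the ce11 genome build. Read numbers are not given in the sources used here, so the depth of each library is unknown.

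The deposited list of peaks that passed the authors' reproducibility threshold held 469 peaks, called thresholded peaks from here on. Their signal, a value per peak from the authors' caller, ran from 82.9 to 601 with a median of 115. They were the 469 peaks of highest signal among the 28882 of the list called on both replicates pooled. All 469 were overlapped by a peak in the full list of each replicate, but those lists held 30000 peaks each. Within the 469 peaks of highest signal of each replicate, 294 peaks of replicate 1 (62.7%, exact 95% interval 58.1 to 67.1) overlapped one of replicate 2, where circular shifts of positions gave 0.362% (one-sided permutation p = 1e-05, the smallest that 100000 draws can give). Of the thresholded peaks, 385 (82.1%) were overlapped by a top peak of replicate 1, 359 (76.5%) by one of replicate 2, 295 (62.9%) by both and 20 (4.26%) by neither. In the upper part of the ranking 226 of 234 peaks (96.6%, 93.4 to 98.5) had a top peak in both replicates, and below it 69 did (29.4%, 23.6 to 35.6). This contrast follows largely from the construction, because the signal is pooled from the same replicates and each list was ended at rank 469. Across the 469 peaks, which are not independent replicates, Spearman's rho of the ranks in the replicates was 0.680.

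**Figure D1:**
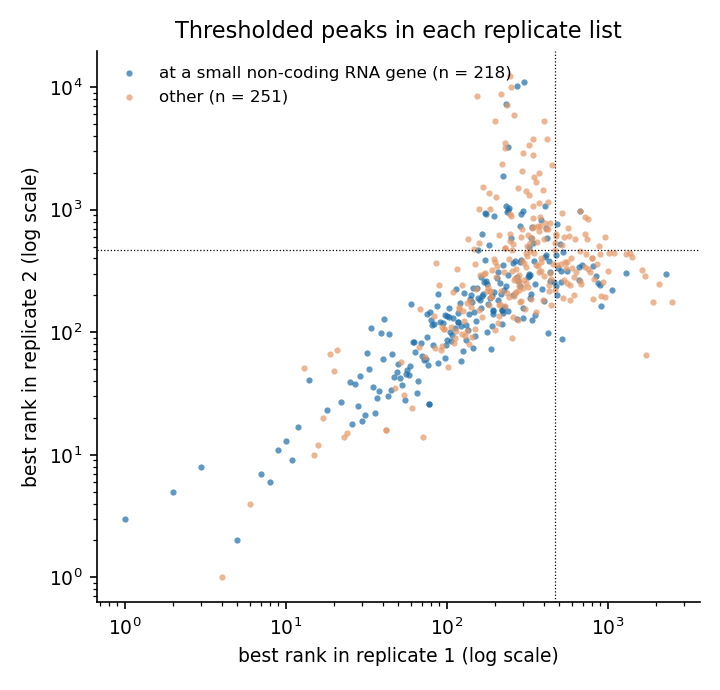
Best rank of the overlapping peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for each of the 469 thresholded peaks, with 218 peaks at small non-coding RNA genes in blue and the other 251 in orange; dotted lines mark rank 469. Peaks of high rank in one replicate ranked high in the other, and the spread widened near the dotted lines.

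Small non-coding RNA genes were the most enriched class of location among those tested. The summit lay within 200 bp of a tRNA, snoRNA, snRNA or rRNA gene in 218 of 469 thresholded peaks (46.5%, exact 95% interval 41.9 to 51.1), against 0.554% after circular shifts within chromosomes, which is 84.0-fold more (two-sided permutation p = 2e-05, the smallest that 100000 draws can give). Pooled peaks that overlapped no thresholded peak are called background peaks from here on. Of these 28330 peaks, 331 (1.17%) lay that close. Of the next 469 pooled peaks by signal, 47 did (10.0%, two-sided Fisher's exact p = 5.36e-37 against the thresholded peaks), a comparison chosen after the result was seen. The 218 peaks comprised 160 at tRNA genes (34.1%, 29.8 to 38.6), 50 at snoRNA genes (10.7%, 8.02 to 13.8) and 8 at snRNA genes (1.71%, 0.739 to 3.33), each above its shifted share (permutation p = 2e-05 for each). No summit lay near any of the 20 annotated rRNA genes, and no pooled peak did, although the pooled list also holds background. Lack of binding at rRNA genes can therefore not be told from a lack of callable peaks there. Counted by gene, 174 of 612 tRNA genes (28.4%, 24.9 to 32.2), 50 of 346 snoRNA genes (14.5%, 10.9 to 18.6) and 7 of 129 snRNA genes (5.43%, 2.21 to 10.9) had a thresholded summit within 200 bp.

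The thresholded peak of highest signal (601) lay 65 bp from the snoRNA gene W03C9.9 on chromosome II (11960898 to 11960959). The other 4 non-coding genes nearest the strongest peaks were also snoRNA genes. These were C51F7.4 on V (12303599 to 12303693, signal 582, summit within the gene), ZK265.10 on I (8259437 to 8259498, signal 564), T06C12.16 on V (15873855 to 15873926, signal 540) and T03F7.8 on V (11314258 to 11314332, signal 488). Each of the 5 had a peak ranked 8 or better in both replicate lists. Over the 50 snoRNA peaks the median summit lay 44 bp upstream of the annotated 5′ end (position -44, quartiles -54.8 and -23.5). Over the 160 tRNA peaks it lay inside the gene, at position 17.5 from the 5′ end (quartiles 3.5 and 45.5, median tRNA gene length 72 bp). The share at non-coding RNA genes was 68.1% in ranks 1 to 47 and 78.7% in ranks 48 to 94, and 17.4% in ranks 424 to 469. Only 122 of the 469 summits lay inside such a gene, so the share depended on the distance allowed.

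**Figure D2:**
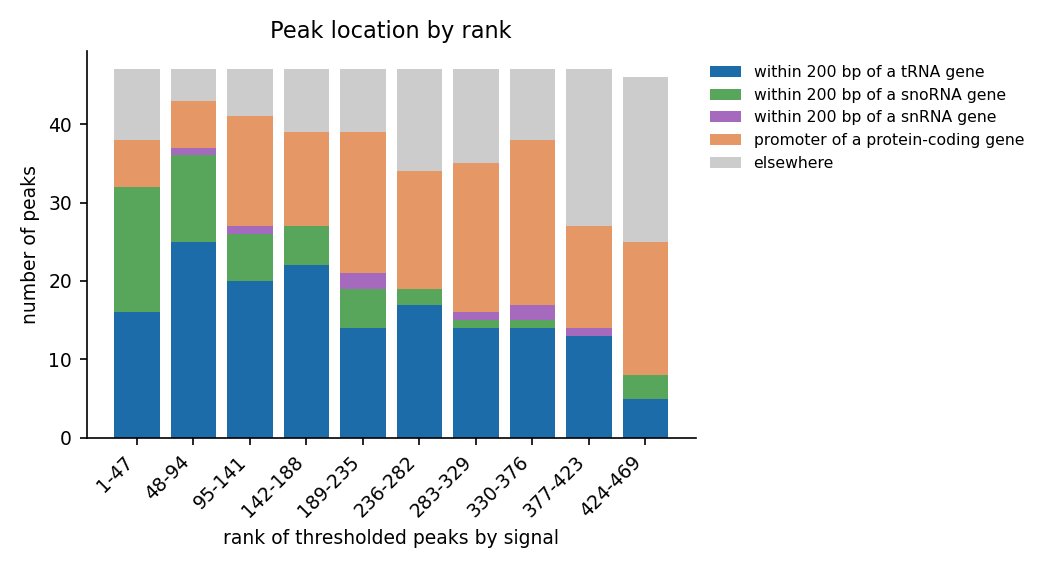
Number of thresholded peaks (y axis) by location in 10 bins of rank by signal (x axis), each peak counted once in the order tRNA, snoRNA, snRNA, promoter, elsewhere. Peaks at tRNA and snoRNA genes made up 32 of the first 47 peaks, and 8 of the last 46.

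Promoters of protein-coding genes also held more summits than their share of the genome, and exons held fewer. A promoter (500 bp upstream to 100 bp downstream of an annotated 5′ end) contained 170 thresholded summits (36.2%, 31.9 to 40.8), 3.32 times the shifted mean of 10.9% (two-sided permutation p = 2e-05, the smallest possible). The share was 13.4% in background peaks (Fisher's exact p = 8.07e-35, two-sided) and 26.9% in the next 469 peaks (Fisher's exact p = 0.00249). Gene bodies outside promoters contained 157 summits (33.5%, 29.2 to 37.9), below the shifted mean of 59.3% (permutation p = 2e-05) and the 61.7% of background peaks (Fisher's exact p = 2.13e-34). Exons accounted for most of that deficit, with 20 summits (4.26%, 2.62 to 6.51) against 26.3% after shifts (permutation p = 2e-05). Introns held 137 (29.2%) against 32.9% (permutation p = 0.0962) and intergenic sequence 142 (30.3%) against 29.8% (permutation p = 0.848), so neither was separated from shifted positions over all 469 peaks. Against background peaks the intergenic share was higher (24.9% there, Fisher's exact p = 0.00834), and the intron share was not separated (32.4% there, Fisher's exact p = 0.149). In a split chosen after seeing the data, the intron share differed between the 218 peaks at small non-coding RNA genes, with 98 in introns (exact 95% interval 38.2 to 51.8%), and the other 251, with 39 (15.5%, 11.3 to 20.6).

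**Figure D3:**
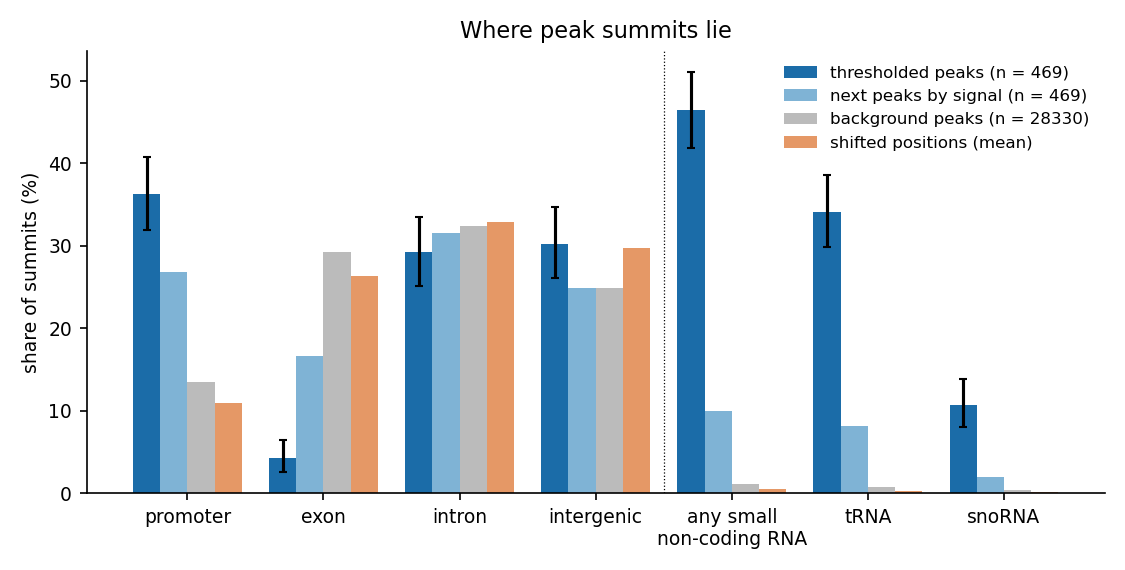
Share of peak summits (y axis, %) in 4 exclusive classes left of the dotted line and, right of it, within 200 bp of small non-coding RNA genes, which overlap those classes. Bars give the 469 thresholded peaks with exact 95% intervals, the next 469 pooled peaks, the 28330 background peaks and the mean of shifted positions; 46.5% of thresholded summits lay at a small non-coding RNA gene against 1.17% of background summits.

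A 5′ end of a protein-coding gene lay within 1000 bp of 261 thresholded summits (55.7%), which were assigned to 253 genes. Among the 25 such genes at the peaks of highest signal, 15 had a peak that lay within 200 bp of a tRNA or snoRNA gene, so the peak cannot be attributed to the protein-coding gene by position. For example, the peak assigned to the serpentine receptor gene sre-23 (signal 564) had its summit 62 bp from the snoRNA gene ZK265.10. That of the potassium channel gene twk-5 (345) lay 56 bp from the snoRNA gene B0334.12. Those of the guanylate cyclase gene gcy-33 (284), the collagen gene col-85 (269) and sor-3 (241) fell inside tRNA genes. The peaks of C04A11.5 and F28H6.7 also fell inside tRNA genes, and that of C28G1.2 lay 25 bp from one. Those of T02E1.2, Y43F8C.7, T27A3.8, wrt-3, F55A11.11, cfim-2 and chst-1 lay 11 to 75 bp from snoRNA genes.

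The other 10 had no such gene within 200 bp. K12H4.5 had the strongest of these peaks, with its summit at position 8043984 of chromosome III, 503 bp upstream of the 5′ end (position -503, signal 600), ranked 4 in replicate 1 and 1 in replicate 2. The peak of ears-2, annotated by RefSeq as a mitochondrial glutamyl-tRNA synthetase, was centred at position 390494 of IV, 26 bp upstream of the 5′ end (position -26, signal 314). Peaks in promoters were also found at rpl-3, a ribosomal protein of the large subunit (III, 3867587, signal 310), T13C5.6 (X, 6207864, signal 277), the ataxin-2 homolog atx-2 (III, 10461335, signal 265), tasp-1 (III, 10759230, signal 258) and idhg-1, a mitochondrial isocitrate dehydrogenase subunit (III, 4568754, signal 252). That of the alpha tubulin gene tba-7 (III, 11371463, signal 257) was in an intron of the gene. The peak assigned to M01F1.9 (III, 3500039, signal 303) lay upstream of it, in an intron of the neighbouring gene M01F1.8, and that of ftt-2 (X, 11605934, signal 325) was intergenic. All 25 peaks ranked 78 or better in both replicate lists.

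Genes for cytosolic ribosomal proteins had a thresholded peak nearby more often than other genes. Of 55 with any pooled peak within 1000 bp of the 5′ end, 7 had a thresholded peak, where 1.65 were expected (odds ratio 4.82, Fisher's exact adjusted p = 0.0262 over 22 lists). They were rpl-3, rpl-15 (signal 186), rps-28 (165), rps-1 (131), rps-4 (113), rpl-35 (105) and rpl-24.2 (94.7), of which the last 3 were named after their values were seen. All 7 peaks were in promoters and none lay within 200 bp of a small non-coding RNA gene. The call did not hold on the 469 top peaks of replicate 2 alone (odds ratio 4.34, Fisher's exact adjusted p = 0.0912) or on the upper 234 thresholded peaks (odds ratio 5.49, adjusted p = 0.177 by Fisher's exact test). No precipitation from animals without the tag was analysed here, so peaks at these genes, as at tRNA and snoRNA genes, were not compared with enrichment that does not depend on the tagged protein.

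In the lists, a gene with a thresholded peak within 1000 bp is called bound whatever the cause of the peak. None of the other 21 lists passed the same test (adjusted p = 1 by Fisher's exact test for each, and only 1 list of the 22 below 0.05 before adjustment). Chromatin and DREAM-type regulators had 3 of 38 genes bound, namely lin-35, the retinoblastoma homolog (signal 120), the histone acetyltransferase gene cbp-1 (117) and the SWI/SNF gene swsn-3 (103). The respiratory chain list had 2 of 23, nuo-2 (101) and cox-6A (96.9). The chaperone list 2 of 35, dnj-29 (172) and dnj-9 (100.03), and the nuclear hormone receptor list 2 of 110, nhr-255 (217) and nhr-47 (114). The peaks of cox-6A and nhr-255 lay at a snRNA and a tRNA gene. Lists with 1 bound gene were translation factors (eif-3.C, signal 176, of 25), aminoacyl-tRNA synthetases (ears-2, of 17) and proteasome subunits (pbs-4, signal 83.2, of 21). So were cell cycle and DNA replication (mcm-10, signal 93.4, of 44) and Wnt and Notch signalling (mig-5, signal 96.7, of 26). No gene was bound among core and variant histones (22 with a pooled peak), Sm and snRNP proteins (11), homeobox factors (38), T-box factors (5), early lineage specification (21) or autophagy and lysosome (30). Nor was any gene of a tissue list bound. The tissue lists were muscle (29), neurons (25), intestine (17), epidermis and cuticle (31), pharynx (22) and germline (18). At most 1.14 bound genes were expected in any of these lists, so depletion was not detectable.

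Chromosome X carried more thresholded peaks than its length predicts and chromosome V fewer. On X there were 106 peaks (22.6%, 18.9 to 26.7) for 17.7% of the nuclear genome (exact binomial adjusted p = 0.0128 over 6 chromosomes) and 16.3% of background peaks (Fisher's exact adjusted p = 0.00123). On V there were 55 (11.7%, 8.96 to 14.99) for 20.9% of the length (exact binomial adjusted p = 1.62e-06) and 18.1% of background peaks (Fisher's exact adjusted p = 0.00123). Chromosome III, with 88 peaks (18.8%), exceeded its 13.7% of the length (exact binomial adjusted p = 0.00742) but not its 16.3% of background peaks (Fisher's exact adjusted p = 0.294), and I, II and IV passed neither test. The excess on X was not separated from length in the 469 top peaks of replicate 2 alone (20.3%, exact binomial p = 0.146). It was found in the peaks at small non-coding RNA genes, 73 of 218 of which were on X (33.5%, 27.3 to 40.2), and not in the other 251, with 33 on X (13.1%, 9.23 to 17.97). Chromosome arms, taken as the 2 outer parts when each chromosome is divided into 3 equal parts, held 63.5% of thresholded and 71.1% of background summits (Fisher's exact p = 0.000476). Against their 66.7% of the length this share was not separated (exact binomial p = 0.156), and on X arms held 67.9% of thresholded and 69.3% of background summits (Fisher's exact p = 0.750).

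The sequence within 50 bp of the summits was richer in G and C than that of background peaks, with a mean of 49.7% ± 7.48 (SD, 469 windows) against 40.7% ± 8.70 (SD, 28330 windows). Against 1407 background windows matched on GC content, 168 of 2080 canonical 6-mers were more frequent and 133 less frequent (Fisher's exact test with Benjamini-Hochberg adjustment at 0.05). The lowest adjusted p was that of CGAACC, in 19.2% of thresholded windows against 3.34% (odds ratio 6.87, Fisher's exact adjusted p = 2.22e-22). The others were GTTCGA, in 21.5% against 4.83%, ACCACT, in 19.4% against 5.26%, GAACCC, in 76 of 469 against 55 of 1407 windows, and AACCAC, in 14.7% against 3.84%. Each window was counted as 1 observation, although 160 of the 469 summits lay at tRNA genes. Of 612 tRNA genes, 449 have a sequence that occurs more than once. Windows are therefore not independent, the p-values may be too small and the counts of 6-mers that passed too large. Of the less frequent 6-mers, CATCAG had the lowest adjusted p, in 0.213% against 6.18% (odds ratio 0.0324, Fisher's exact adjusted p = 4.33e-08). It was followed by CTGGAA, in 2.13% against 9.31%, GCTGGA, in 1.49% against 8.10%, CCTCCA, in 2.77% against 10.1%, and GCTCCA, in 3.198% against 10.7%. The background windows were matched on GC content and not on location, and exons held 4.26% of thresholded against 29.3% of background summits. Whether the less frequent 6-mers reflect this difference in location was not tested. None of the 5 more frequent 6-mers passed once the 218 peaks at small non-coding RNA genes were left out, an alternative chosen after seeing the data (odds ratios 0.617, 0.839, 1.03, 0.264 and 1.54 in the same order). Of the less frequent ones, CCTCCA and GCTCCA did not pass there either (odds ratios 0.421 and 0.498). Leaving out a replicate brought the odds ratio of CATCAG to 0.277 on replicate 2 alone and 0.164 on replicate 1 alone. GCTGGA went from 0.172 to 0.272 and 0.354, and GCTCCA from 0.275 to 0.364 and 0.419, in the same order. Of the more frequent ones, AACCAC went from 4.32 to 2.49 and 3.12, and still passed. CCTCCA went from 0.254 to 0.466 on replicate 2 alone, and did not pass on replicate 1 alone (odds ratio 0.563, Fisher's exact adjusted p = 0.113). Against flanking windows GCTGGA, CCTCCA and GCTCCA did not pass (odds ratios 0.416, 0.927 and 0.742), while the odds ratios of CGAACC, GAACCC and ACCACT rose to 14.6, 10.5 and 7.55. With windows of 100 bp either side that of CATCAG was 0.303 and that of AACCAC 2.12.

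At the native locus of the tagged gene, Y22D7AL.16 on the minus strand of chromosome III (1662104 to 1665216), 3 thresholded peaks lay within 20 kb, where random windows of chromosome III held 0.274 on average (one-sided permutation p = 0.00987). Their summits were at 1653896 in cht-4 (signal 137, rank 165), at 1659765, 98 bp from the 5′ end of Y22D7AL.15 (signal 103, rank 292), and at 1668652, 33 bp from the 5′ end of glb-30 (signal 87.4, rank 408). The replicates differed here: 8 of the 469 top peaks of replicate 1 fell in the window (permutation p = 0.00204) and 2 of those of replicate 2 (permutation p = 0.0381). At unc-119, also on III (10902641 to 10908935), no thresholded peak lay within 20 kb, and the nearest was 45582 bp away.

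**Figure D4:**
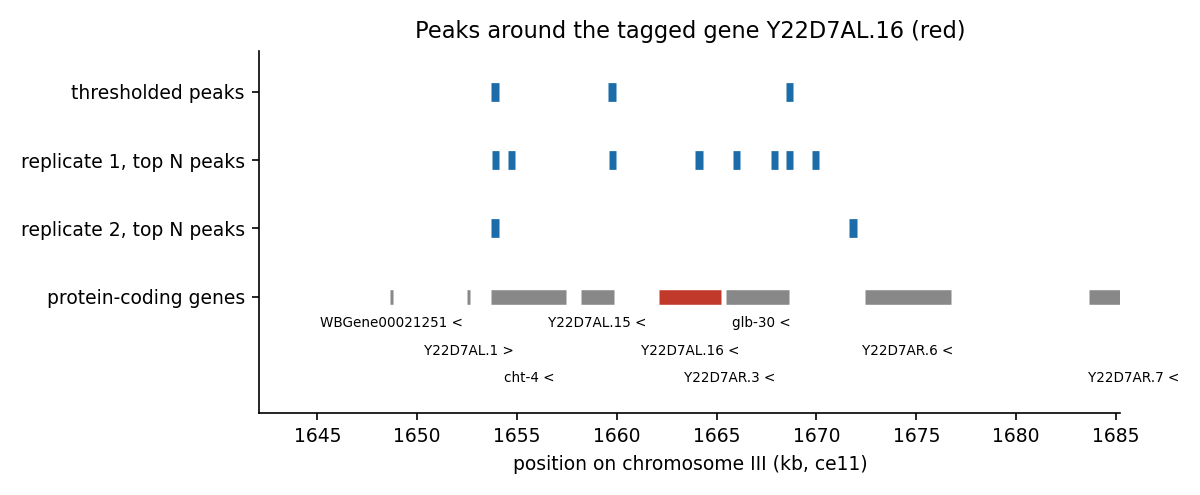
Positions on chromosome III (x axis, kb, ce11) of thresholded peaks, of the 469 top peaks of each replicate and of protein-coding genes within 20 kb of Y22D7AL.16 (red); < and > give the strand. There were 3 thresholded peaks, 8 peaks of replicate 1 and 2 of replicate 2, with 1 position, in cht-4, shared by the 3 lists.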

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

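The settings that leave out the 218 peaks at small non-coding RNA genes were chosen after seeing the data. No paired analysis was possible because there is 1 group. The shares in promoters, gene bodies and at non-coding RNA genes kept their direction and their side of the threshold under every alternative run for them. So did the replicate overlap, and the peaks near Y22D7AL.16 and unc-119 when thresholded or top peaks were counted. In the full lists, which also hold background, the excess near Y22D7AL.16 was not separated in replicate 1 (22 peaks against 15.2 in random windows, one-sided permutation p = 0.117). Nor was it in replicate 2 (18 against 14.8, permutation p = 0.276), and the pooled list had 24 against 14.7 (permutation p = 0.0400). With 1 replicate left out the promoter share was 32.8 to 34.3% and the non-coding RNA share 43.1 to 43.3%. The latter depended on distance and rank, with 122 of 469 summits inside the genes, 46.9% within 500 bp and 61.5% on the upper 234 peaks. The number of peaks fell by construction to 234 in the upper part of the ranking and to 295 with support in both replicates, and ce10 gave 449. The share on X lay at 20.3 to 21.7% with 1 replicate left out, where for replicate 2 alone the cause of the lost call was not tested, and at 13.1%, below the share of length, without peaks at non-coding RNA genes. Lists that passed numbered 0 on the upper 234 peaks and 0 to 1 with 1 replicate left out, where fewer ribosomal protein genes were bound (4 and 6 in place of 7). The 301 6-mers that passed became 189 on the upper 234 peaks and 85 without peaks at non-coding RNA genes, both with fewer windows, 462 with windows of 100 bp either side, and 834 against flanking windows, which were not matched on GC; with 1 replicate left out there were 226 to 238. Without peaks at non-coding RNA genes the odds ratios of CGAACC, GTTCGA and GAACCC went below 1 (0.617, 0.839 and 0.264). Odds ratios that moved by more than 1.5 times and still passed were, against flanking windows, those of CGAACC (14.6), GAACCC (10.5), ACCACT (7.55) and CATCAG (0.0551). With 100 bp either side they were those of AACCAC (2.12), CATCAG (0.303), CTGGAA (0.394), GCTGGA (0.416) and CCTCCA (0.593). On the upper 234 peaks they were CATCAG (0), CTGGAA (0.134) and CCTCCA (0.135), and with support in both replicates CATCAG (0) and GAACCC (7.85). Without peaks at non-coding RNA genes they were GCTGGA (0.0695) and CATCAG (0.0677). Those with 1 replicate left out are given in the results above. Of the 18 peaks named as members of a list, 14 were within the top 469 of replicate 2 and 16 within that of replicate 1. Unknown depth limits every statement on peaks of low signal.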

Other observations

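Of the tests in this part, those of the next 469 peaks at non-coding RNA genes, of single tRNA sequences, of peaks on X and of 6-mers away from non-coding RNA genes, of the promoter shares of the 218 and 251 peaks, of tRNA genes by amino acid and on X against autosomes, and of the 6-mer in even-ranked peaks and in their promoters were chosen only after the result was seen. So were the genes rpr-1 and mrpr-1. Both are annotated non-coding RNA genes outside the 4 biotypes and carried strong peaks. They were picked by name, and other genes of this kind were not screened. Their peaks are counted among the 251 peaks away from small non-coding RNA genes. The RNA of RNase P, rpr-1 on chromosome I (13463955 to 13464207), had a summit 12 bp away (signal 232, rank 59), and that of RNase MRP, mrpr-1 on II (7200233 to 7200418), had one within the gene (signal 212, rank 71). No group of tRNA genes by amino acid stood out: of 21 groups over 607 tRNA genes, 0 passed Fisher's exact test at 0.05 before or after adjustment, with tRNA-Ala bound at 14 of 34 genes and tRNA-Gln at 5 of 27. The 251 peaks away from small non-coding RNA genes were mostly in promoters (141, 56.2%, exact 95% interval 49.8 to 62.4), unlike the 218 at such genes (29, 13.3%, 9.09 to 18.5; Fisher's exact p = 5.71e-23), 98 of which (44.95%) were in introns. Sequence that the assembly masks as repetitive covered most of the summit window in 7 of the 218, 30 of the 251 and 6010 of the 28330 background peaks (3.21%, 11.95% and 21.2%).

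Peaks at snoRNA genes may mark those with a promoter of RNA polymerase III, whose box B element has the consensus GWTCRANNC. This was tested as a hypothesis before its result was seen, but not on an independent set of peaks. The consensus allows the sequence GTTCGA, which was found in 21.5% of thresholded windows against 4.83% of GC-matched background windows. Those thresholded windows include the ones at snoRNA genes, so the p-value of the sense strand is not independent evidence. The element was present on the sense strand between 150 bp upstream and 50 bp downstream of the 5′ end in 30 of 50 snoRNA genes with a thresholded summit (60%) and in 23 of 296 others (7.77%; odds ratio 17.8, Fisher's exact p = 4.24e-16, two-sided). On the antisense strand it was found in 2 of 50 and 13 of 296 (Fisher's exact p = 1). Among the 96 other snoRNA genes with a pooled peak, 12 had it (12.5%). Median summits lay 44 bp upstream of the snoRNA 5′ end and inside tRNA genes. Where the element lay relative to each summit was not measured, so these positions do not test the hypothesis. The polymerase was not measured either.

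Technical explanations were weighed for the peaks at small non-coding RNA genes. An equal preference of all called peaks for these genes is argued against as the whole cause by the next 469 peaks, of which 10.0% lay there against 46.5% (Fisher's exact p = 5.36e-37). That 10.0% is itself above the shifted share of 0.554%, so a preference that grows with signal stays open. Reads shared between identical tRNA genes could add to the pattern. The tRNA genes whose sequence occurs more than once had a summit in 138 of 449 cases (30.7%). Those with a single sequence had one in 36 of 163 (22.1%, odds ratio 1.57, Fisher's exact p = 0.0424). This test counted genes as independent, but 174 tRNA genes had a summit and tRNA peaks numbered 160. Some genes therefore shared a peak, and the call is close to the threshold. Exact copies are argued against as the whole cause, since 32 summits (6.82%) lay near single sequences and near no repeated one. Shifts gave 0.0746% there (permutation p = 2e-05). Near-identical copies were not counted as repeated, so reads shared with them stay open as an explanation. Enrichment of highly transcribed loci irrespective of the tagged protein stays open, for these genes and for those of ribosomal proteins, as no precipitation from animals without the tag was analysed here and the design names no group to test a biological explanation with.

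For the excess of peaks on X, over-representation of X among all called peaks is argued against by the 16.3% of background peaks (Fisher's exact p = 0.000411). So are a few dense clusters, since merging summits within 10 kb left 99 of 431 clusters on X (22.97%, exact binomial p = 0.00536). The location of tRNA genes may account for it: 276 of 612 lie on X (45.1%), and peaks away from non-coding RNA genes were on X in 13.1% of cases, not above the 17.7% of length (exact binomial p = 0.0681). tRNA genes on X were bound at 29.0% (80 of 276) and those on autosomes at 28.0% (94 of 336; Fisher's exact p = 0.788). No biological explanation was tested.

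The 3 thresholded peaks around Y22D7AL.16 could come from extra copies of that region on the transgene. Extra copies would need more peaks than random windows have (3 against 0.274, permutation p = 0.00987). That excess is the pattern to be explained, so it adds no support for extra copies over other explanations. The absence of thresholded peaks within 20 kb of unc-119 gives no sign of an effect of extra copies at the marker gene. How much of unc-119 the transgene holds is not given in the sources used here. The density of gene starts is argued against, since 28827 random windows with a similar number of 5′ ends (8, within 20%) held 0.294 peaks on average (permutation p = 0.0124). Binding of the protein at its own locus stays open and untested, and the 8 top peaks of replicate 1 against 2 of replicate 2 show that the count differs between replicates.

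Peaks away from small non-coding RNA genes may share a sequence of their own. Against GC-matched background, the 6-mers of lowest p were GCGCAC, in 16.3% of these windows against 3.32%, and ACGCGC, in 17.5% against 3.98%. The 6-mer of lowest p in the odd-ranked peaks, CGCAAG (25 of 126), was also more frequent in the even-ranked ones, with 14 of 125 (11.2%) against 7 of 375 background windows (1.87%; odds ratio 6.63, Fisher's exact p = 4.55e-05). An equal frequency of CGCAAG in all promoter peaks is argued against by the even-ranked promoter peaks, which played no part in choosing it. Of these, 11 of 64 (17.2%) held it against 5 of 192 background promoter peaks of matched GC content (2.60%, odds ratio 7.76, Fisher's exact p = 0.000172). Background peaks had lower signal by construction, so a sequence common to promoters with strong peaks, whatever the tagged protein, stays open. For the promoter share itself, an equal preference of all called peaks for promoters is argued against as the whole cause by the next 469 peaks (26.9% against 36.2%, Fisher's exact p = 0.00249). That 26.9% is itself above the shifted mean of 10.9%, so a preference that grows with signal stays open here too. Whether the sequence is bound by Y22D7AL.16 was not tested.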
